A study of Mus musculus with 6 samples.

How the data were processed

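RNA sequencing was measured in 6 libraries of sorted cells from mouse embryonic palatal shelves. Per the labels, the shelves were dissected out, digested with trypsin-EDTA at 37 °C for 4 minutes and passed through a 40 µm strainer, and cells with red fluorescent protein (RFP) from an Osr2RFP allele were sorted. Libraries were made from 150 to 500 ng of RNA with poly A selection and 15 cycles of PCR and were read as pairs of 75 bases. The labels name both a Nextera and a TruSeq stranded kit, and 2 models of Illumina HiSeq, and the values do not settle which was used. The mice had a mixed background. Nothing in the labels says whether each library came from 1 embryo, so the p-values measure only the spread between these libraries.

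Each library has its own table with 1 line per RefSeq transcript (31579 lines). The values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, computed by the authors with Cufflinks, whose version is not given in the sources used here. The labels name TopHat 1.4.1 and Bowtie 0.12.7 and the builds mm10 and mm9. Of the lines matched to an annotated RefSeq transcript, 97.5% lay inside the gene's GRCm38 (mm10) locus, so positions are given on that build. The deposited tables also hold a coverage signal, the mean depth of read bases over a transcript, which was used only to estimate depth. Summed over transcripts it gives 14100000 to 17970000 fragments per library if every fragment was read as 2 × 75 bases. The files give no read counts, so no counting intervals were computed, and the spread between libraries is the measure of precision.

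Values were summed over the transcripts of each gene symbol (23443 symbols). The 25 symbols with a transcript whose estimate had failed in any library were left out. Genes were tested when they had at least 1 FPKM in at least 2 of the 6 libraries (10799 genes), on log2(FPKM + 1), with values as the authors scaled them. Folds are powers of 2 of differences on that scale, so they understate the change of genes with low FPKM. Genes were marked as of uncertain assignment when all transcripts were under 200 bases, when the symbol had several separate loci, or when it shared at least 80% of a locus with another symbol.

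Tests were limma 3.58.1 moderated tests with an intensity trend, in R 4.3.3, two-sided, with the Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fit with 1 mean per group gave the genotype contrast at E13.5 and the interaction of genotype and age. The lone E12.5 libraries of that fit are assumed to vary like the E13.5 libraries. An additive fit of age and genotype gave the genotype contrast across both ages and the age contrast. At E12.5 alone, with 1 library per group, differences were described by size (1 on the log2 scale, at 5 FPKM or more in the higher library). For that age, gene lists were placed by the percentile of their median among 10000 random lists matched on expression in 20 bins.

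The 29 gene lists hold 636 genes, of which 633 were found (7 by an older symbol) and 436 were tested. The 23 lists with at least 5 tested members were tested with limma camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, adjusted over the lists. The estimated correlation rests on 2 residual degrees of freedom at E13.5 and 3 in the additive fit. A list that does not pass with it is therefore not shown to be unchanged. The groups, the tests, the lists, most alternatives and the rule for named genes were chosen before the data were examined. The osteogenesis, BMP and semaphorin lists were written in the knowledge that the study reports on genes of those classes in these samples.

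The rule names Osr2. For the genotype contrast at E13.5 it then names the 12 higher and 12 lower genes with the largest change among those past the threshold, with a mean of at least 5 FPKM in 1 group and both mutant libraries beyond both control libraries. Where a direction had under 12, those there were are named, and under 8 it was to be filled to 8 by the smallest unadjusted p. Both ages together and age follow the same rule, with separation within each age and between ages. At E12.5 it names the 10 genes each way with the largest change, and for the interaction up to 5 each way. From each list it names members past the threshold, and otherwise up to 4 with the smallest p. Symbols of the forms Gm with a number or ending in Rik, and those starting with Mir, Snor, Scarna or Rn, are left out of names. List members not past the threshold are named only with an unadjusted p under 0.05, a restriction chosen after the values were seen. For age, where lists had many members past the threshold, mostly the 4 with the smallest p were followed across alternatives. Osr2 was also followed for both ages and for age, chosen after its values were seen.

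The alternatives changed 1 choice at a time: the pseudocount (0.1 or 5), the filter (none, or a mean of at least 1 or 5 FPKM), the scaling (1 FPKM sum, median ratio or quantile), the prior (no trend, or robust), the transcript with the highest mean in place of the sum, the E13.5 libraries alone, limma treat at 0.5, and each library left out in turn. Fits without genes of uncertain assignment and without genes on X and Y were added after the data were seen. For 3 lists the members called by age were also counted with each library left out, chosen after the values were seen. With an E12.5 library left out, the additive fit takes the age difference from the genotype still present at E12.5. Its genotype difference is then that of the E13.5 libraries. Simulated data had the spread of these libraries. Changes were added on the log2(FPKM + 1) scale, only to genes with a mean of at least 5 FPKM, so recovery at lower levels is unknown. On these data, genotype changes at E13.5 of 1.5-, 2-, 3- and 4-fold were recovered for 6%, 56%, 98% and 100% of 50 genes each, and 4.4% of calls were false. In the same simulation, no interaction of any of these sizes was recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.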

Results

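Osr2 encodes a zinc finger transcription factor needed for growth of the palatal shelves. The study profiled palatal mesenchyme cells that carried an RFP reporter at Osr2, from mutant embryos (Osr2RFP/-) and control embryos (Osr2RFP/+). There were 2 mutant and 2 control libraries at embryonic day 13.5 (E13.5), and 1 of each at E12.5. The E12.5 mutant library had an FPKM sum of 189855 and an estimated 17970000 fragments, and the E12.5 control library 154919 and 17090000. At E13.5 the sums were 166213 and 162011 in mutant replicates 1 and 2, and 167058 and 158208 in control replicates 1 and 2, with estimated fragments of 15790000, 16380000, 14100000 and 16700000. Each library had 10261 to 10478 genes at 1 FPKM or more, and its 50 highest genes took 16.4% to 20.1% of its FPKM. The first principal component of the 6 libraries (44.4% of the variance) separated the ages. The second (19.3%) placed the mutants at 10.03, 7.24 and 17.71 and the controls at -13.61, -8.38 and -12.98.

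The libraries also differed in ways the groups do not explain. The E12.5 pair and E13.5 mutant replicate 2 had 129, 141 and 138 FPKM of Xist, the RNA of the inactive X chromosome, and the other 3 libraries had 0.0194 FPKM or less. Ddx3y, a Y-linked gene, had 3.56 to 3.97 FPKM in those other 3 libraries and at most 0.00281 in the rest. The title number before the hyphen was 2962 for both E12.5 libraries, 3047 for E13.5 mutant replicate 1 and 3048 for the remaining E13.5 libraries. The labels do not say what these numbers stand for.

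Osr2 itself (chromosome 15, 35296112 to 35303305) was lower in the mutants at E13.5. Its level was 78.4 ± 14.1 FPKM (SD, n = 2) in mutants and 145 ± 9.50 (SD, n = 2) in controls, a difference of -0.89 on the log2 scale (SE 0.167, limma adjusted p = 0.0409). At E12.5 it had 162.8 FPKM in the mutant and 215.1 in the control. The labels do not say which part of the gene the alleles lack, and transcripts of the 2 alleles are not told apart in these values. The Osr2 call was lost without E13.5 control replicate 1 (adjusted p = 0.217), without control replicate 2 (adjusted p = 0.392) and under each of the 3 other scalings (adjusted p = 0.0582, 0.0664 and 0.0539), within a range of 0.00523 to 1 over its alternatives with all libraries.

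**Figure D1:**
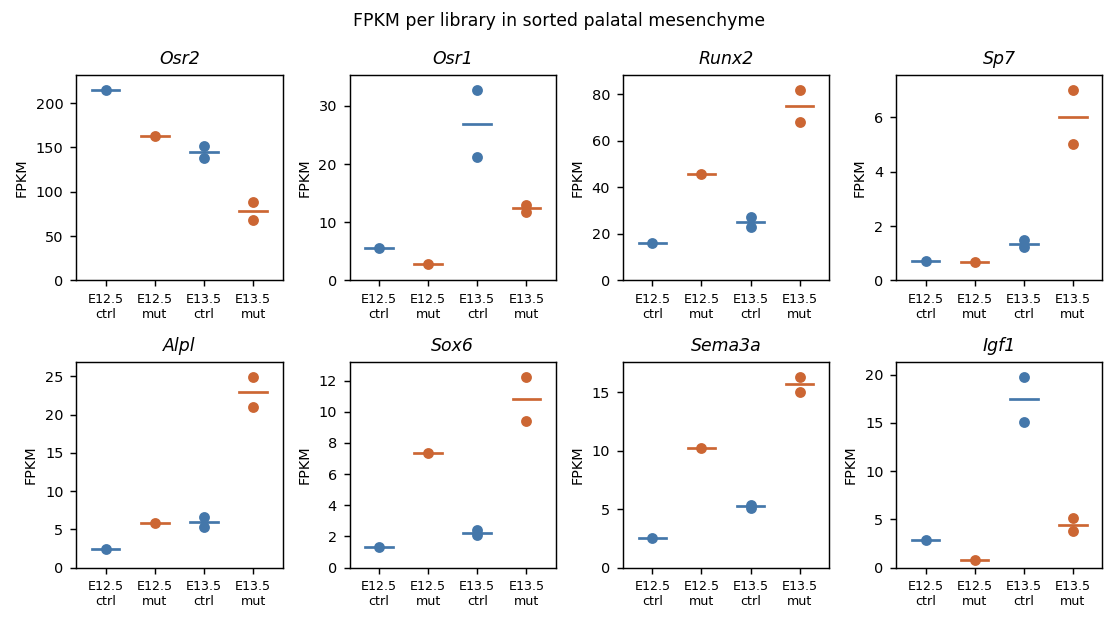
FPKM (vertical axes, from 0) of 8 genes in each group (horizontal axes: E12.5 control and mutant, n = 1 each, E13.5 control and mutant, n = 2 each). Points are libraries and lines are group means. Runx2 is at 45.8 FPKM in the E12.5 mutant against 16.3 in the control, and Igf1 at 0.802 against 2.87.

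The comparison of mutant and control at E13.5 asks which genes differ in these cells when Osr2 is mutated, and it has replicates. Some genes of bone and cartilage formation were higher in mutants (5 of 17 and 1 of 9 tested list members), while neither list passed with an estimated correlation (camera adjusted p = 0.751 each). Runx2 (chromosome 17, 44495987 to 44814797), a master regulator of osteoblast differentiation, rose 2.92-fold, to 75.0 ± 9.90 FPKM from 24.97 ± 3.09 (SD, n = 2 each, adjusted p = 0.0017). Sp7, which acts downstream of Runx2, rose 2.96-fold (adjusted p = 0.00205), and Alpl, the alkaline phosphatase of mineralising tissue, 3.45-fold (log2 1.79, SE 0.147, adjusted p = 0.000697). Sox6 (chromosome 7, 115470872 to 116038744), a transcription factor of chondrocyte differentiation, rose 3.63-fold (log2 1.86, SE 0.146, adjusted p = 0.000688). Of the 10799 genes tested, 139 passed the threshold, 92 higher and 47 lower in mutants, and 9 of the 139 were of uncertain assignment. The other large increases were in Pcp4 (3.93-fold), Mylk (3.29-fold), Thbs2 (3.10-fold), Zeb2 and Mef2c (3.03-fold each), Plk2 (2.94-fold) and Col12a1 (2.93-fold). Mylk encodes myosin light chain kinase, Thbs2 a matricellular thrombospondin, and Zeb2 and Mef2c transcription factors.

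Among genes that fell, Igf1, a growth factor, had the largest change of clear assignment, from 17.4 ± 3.26 FPKM in controls to 4.46 ± 0.959 in mutants (SD, n = 2 each, log2 -1.76, adjusted p = 0.00143). Osr1, the paralog of Osr2, changed by -1.03 (adjusted p = 0.037) and the nuclear receptor genes Nr2f2 and Nr2f1 by -1.005 and -0.85. Prss12 and Gng3 changed by -1.004 and -0.997, Fez1 and Fam43a by -0.88 each, and Rmrp, a noncoding RNA of 275 bases, by -1.24. Hba-a2 (higher), Hba-a1 (lower) and Atp6v0c (lower) also passed the threshold, but reads of these genes may be split with near-identical copies. With the copies summed the differences were -0.36 for Hba-a1 with Hba-a2 (adjusted p = 0.788) and 0.05 for Atp6v0c with Atp6v0c-ps2 (adjusted p = 0.946). Osr1 lost its call without mutant replicate 1 (adjusted p = 0.0606), mutant replicate 2 (0.125) or control replicate 2 (0.148) of E13.5, and under the 3 other scalings (0.0679, 0.121 and 0.106), with an adjusted p of 0.00254 without control replicate 1. Nr2f2, Gng3, Fam43a, Nr2f1 and Fez1 each lost their call without an E13.5 control replicate. With each library left out in turn, their differences ranged from -1.248 to -0.762, -1.163 to -0.831, -1.012 to -0.742, -0.989 to -0.71 and -1.032 to -0.732.

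In the osteogenesis list, 5 of 17 tested members rose in mutants at E13.5 (Runx2, Sp7, Alpl, Mef2c and Bmp3), none fell and 12 did not pass, and 10 rose when adjusted over the list alone. Camera called the list up (adjusted p = 5.15e-10), and its adjusted p was 0.751 with an estimated correlation and 0.164 with fry. In the BMP pathway list, 4 of 24 rose: Bmp3 (2.25-fold), Bmp7 (1.96-fold), Bmp5 (1.89-fold) and Bmper (1.65-fold), with 7 adjusted over the list alone (camera up, adjusted p = 0.00241, and 0.751 with an estimated correlation). In the semaphorin, plexin and neuropilin list, Sema3a (2.66-fold), Sema3d (2.53-fold), Nrp2 (2.07-fold) and Plxnd1 (1.66-fold) rose and Nrp1, a receptor for Sema3a, fell (-0.71), of 25 tested. Adjusted over the list alone these were 7 higher and 3 lower, and camera did not call the list (adjusted p = 0.516). The study chose these 3 classes of genes from these samples, so the direction of the lists is not independent evidence. Bmp7, Bmp5 and Bmper lost their calls without E13.5 control replicate 2 (adjusted p = 0.0614, 0.0808 and 0.222), as did Nrp2 (0.109), Plxnd1 (0.174) and Nrp1 (0.163).

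In the chondrogenesis list, Sox6 rose of 9 tested members at E13.5, and 6 members were higher when adjusted over the list alone. Camera called this list up (adjusted p = 5.58e-05, and 0.751 with an estimated correlation). The retinoic acid pathway list was called down (adjusted p = 0.00033, and 0.751 with an estimated correlation), with Stra6, a retinol transporter, lower (-0.75) of 13 tested and 5 lower when adjusted over the list alone. Glycolysis and hypoxia was called up (adjusted p = 0.00281, and 0.759 with an estimated correlation), with the glycolytic enzyme gene Eno1, of uncertain assignment, 1.80-fold higher of 18 tested (1 adjusted over the list alone). Stra6 and Eno1 lost their calls without E13.5 control replicate 2 (adjusted p = 0.13 and 0.116).

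Of 35 tested palate and facial transcription factors at E13.5, Foxp1 (2.26-fold), Irx5 (2.17-fold), Zfhx3 (1.70-fold) and Sim2 (1.67-fold) rose and Osr1, Lhx8 (-0.72) and Shox2 (-0.70) fell, and 8 were higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.898). Of 18 tooth mesenchyme genes, Runx2 rose and Lhx8 and Fgf10 (-0.81) fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.236). Of 16 FGF pathway genes, the receptor gene Fgfr2 (1.81-fold) and Etv1 (1.98-fold) rose and the ligand gene Fgf10 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.201). Of 51 extracellular matrix genes, Tnn (3.20-fold), Col12a1, Col8a1 (1.78-fold) and Timp3 (1.61-fold) rose and Podn (-0.74) fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.926). Tnn had 3.16 and 2.79 FPKM in mutants and 0.277 and 0.207 in controls. Lgr5, a receptor of the Wnt pathway, rose 1.98-fold of 34 tested Wnt pathway genes (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0909). Klf4 rose 2.01-fold of 20 genes of the dissociation and stress response list (2 adjusted over the list alone, camera adjusted p = 0.745). Zfhx3, Sim2, Lhx8, Fgf10, Fgfr2, Col8a1, Timp3, Podn and Klf4 lost their calls without E13.5 control replicate 2 (adjusted p = 0.173, 0.3998, 0.470, 0.0672, 0.224, 0.402, 0.224, 0.143 and 0.174), and Shox2 and Etv1 without control replicate 1 (0.421 and 0.0636).

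No member passed the threshold at E13.5 in the Hedgehog pathway (18 tested), TGF-beta pathway (18), Notch pathway (9), ephrin and Eph receptor (16), S phase (29), G2 and M phase (29), CDK inhibitor (14), pericyte and smooth muscle (5), cholesterol synthesis (19) and sex-linked (6) lists, and camera called none of them, with adjusted p of 0.0909, 0.628, 0.898, 0.355, 0.16, 0.355, 0.731, 0.747, 0.898 and 0.201. Adjusted over the list alone, the Notch list had 1 higher and 1 lower member and the others none. In the erythroid list, called down (adjusted p = 0.00241, and 0.751 with an estimated correlation), the 2 calls were those of Hba-a1 and Hba-a2. The summed erythroid markers stood at 472 and 263 FPKM in the mutants and 593 and 501 in the controls.

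Markers of 5 other cell types were low in these sorted cells, unlike the erythroid markers above. The summed FPKM of 18 oral epithelium, 14 endothelium, 15 leukocyte, 10 glia and 16 skeletal muscle markers was at most 10.3, 9.33, 7.33, 1.68 and 3.07 in any library. Of the 15 neuron markers, only Gap43, Nefl and Nefm had a mean over the 6 libraries above 0.824 FPKM (28.7, 18.8 and 9.8). Neuron markers summed to 80.5 and 91.6 in E13.5 mutants and 55.5 and 51.4 in controls. Of their 4 tested members Nefm, a neurofilament gene, rose 2.92-fold at E13.5 (3 adjusted over the list alone), with its call lost without mutant replicate 2 (adjusted p = 0.104). No glia marker was tested, and the 1 tested epithelial, 1 endothelial, 1 muscle and 2 leukocyte markers did not pass at E13.5. Adjusted over the list alone, the endothelial marker was higher and 1 leukocyte marker lower.

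The 139 genes came from 4 libraries, and many of them lost their call when an E13.5 library was left out, though Runx2, Sp7, Alpl, Sox6, Sema3a and Igf1 did not. Leaving out an E12.5 library does not change the E13.5 differences, so those fits could hardly lose a call. The count was 75 without E13.5 control replicate 2 and 77 after median ratio scaling, and no gene passed with no filter on low values (1519 genes at an unadjusted p under 0.05).

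At E12.5 a single pair of libraries was compared, with no replicates and no test. The median gene was 0.18 higher in the mutant on the log2 scale (1.14-fold), and after scaling to 1 FPKM sum it was at -0.06, so counts are also given relative to the median gene. The largest increases were in Dlx5, a homeobox gene of bone and jaw formation (16.5 FPKM against 1.15), Ddx26b (19.7 against 3.43), Sox6 (7.32 against 1.31), Plk2 (20.8 against 5.07), Foxp1 (16.8 against 4.36), Sema3a (10.3 against 2.52), Penk, which encodes an opioid peptide precursor (364 against 122), and Mtus1 (5.92 against 1.47). Mecom, with separate loci under its symbol, had 33.1 against 9.69, and Hba-a1 42.8 against 0.0994. The largest decreases were in Hist1h3f (1.30 FPKM against 7.31), the proteoglycan gene Lum (4.95 against 19.2), Erdr1 (97.5 against 286), the immediate early gene Egr1 (5.35 against 16.4), Rmrp (2.27 against 7.91), Zfp503 (9.62 against 20.9), Cox6b2 (4.42 against 9.14), Nt5c (6.16 against 11.6) and Meg3 (28.6 against 50.7), with Atp6v0c at 0.0141 against 6.76. Of 6092 genes with at least 5 FPKM in the higher library, 41 were higher and 16 lower by at least 1, and relative to the median gene 29 and 18.

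The E12.5 list medians were placed among matched random lists within the single pair, so the percentiles do not measure spread between libraries and are not adjusted over the 23 lists. The chondrogenesis list had a median difference of 0.67 (percentile 100 of 10000 random lists), the Wnt pathway 0.35 (percentile 99.99) and extracellular matrix 0.11 (percentile 0.03). The Notch pathway (0.32, percentile 97.4) and osteogenesis (0.33, percentile 96.0) were less far from the random lists, and the other 18 lists lay between percentiles 7.61 (retinoic acid) and 85.3 (tooth mesenchyme). Within the osteogenesis list, Runx2 was higher by 1.44, Alpl by 0.997 and Mef2c by 0.96, and Sp7 had a difference of -0.01. The interaction of genotype and age for Sp7 had an adjusted p of 0.186.

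**Figure D2:**
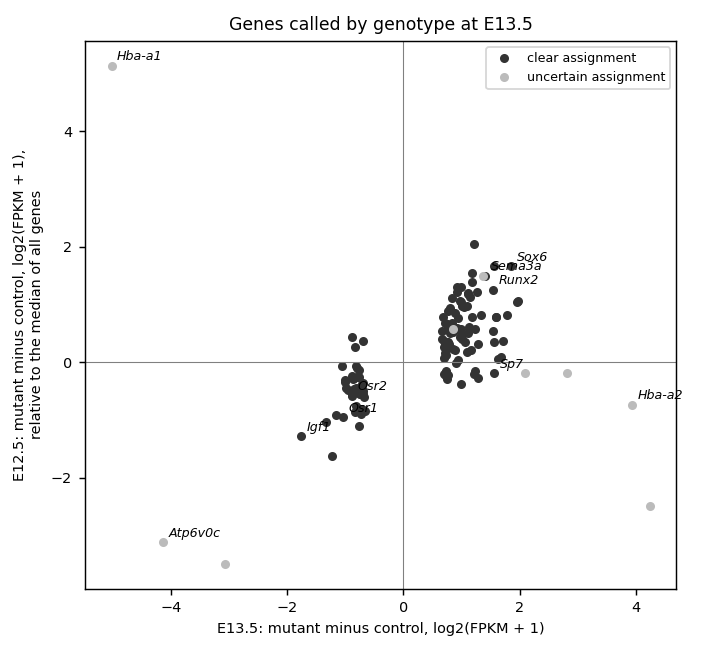
Each point is 1 of the 139 genes past the threshold by genotype at E13.5. The horizontal axis gives its mutant minus control difference at E13.5 and the vertical axis that of the single E12.5 pair relative to the median of all genes, both in log2(FPKM + 1). Of the 92 genes higher at E13.5, 76 are above 0 at E12.5, and of the 47 lower, 43 are below 0.

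Most genes called at E13.5 differed in the same direction at E12.5. Relative to the median gene, 76 of the 92 genes higher at E13.5 were higher in the E12.5 mutant (median of matched random lists 41, highest 59 of 10000). Of the 47 genes lower at E13.5, 43 were lower at E12.5 (random median 25, highest 37). Without genes of uncertain assignment these were 74 of 86 and 41 of 44. The random lists draw genes independently within the single E12.5 pair, so they do not measure spread between libraries.

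The genotype contrast across both ages, 3 mutant and 3 control libraries, gives an average difference over the ages. A gene that differs mainly at 1 age can pass it, as Thbs2 did (1.63 at E13.5 and 0.24 at E12.5, limma adjusted p = 0.0453). With either E12.5 library left out, this contrast becomes that of E13.5. Calls lost in those leave-one-out fits are thus genes that do not pass at E13.5 alone. Sox6 (3.62-fold, log2 1.85, SE 0.114, adjusted p = 0.000162), Plk2 (3.14-fold), Pcp4 (3.32-fold), Ddx26b (2.92-fold), Alpl (2.88-fold), Runx2 (2.85-fold, adjusted p = 0.000679), Sema3a (2.83-fold, adjusted p = 0.000248), Zeb2 (2.62-fold), Mef2c (2.61-fold) and Foxp1 (2.57-fold) rose in mutants. Mecom, of uncertain assignment, was 2.78-fold higher. Dlx5 had a 3.73-fold difference (adjusted p = 0.0404), but was called in 2 of 6 leave-one-out fits, with an adjusted p up to 0.163 without E13.5 mutant replicate 1. Igf1 (-1.54, adjusted p = 0.00249), Rmrp (-1.30), Osr1 (-0.95) and the semaphorin receptor gene Nrp1 (-0.68) fell, as did Darc (-0.91), Cadm3 (-0.74), Ebf3 (-0.68), Gria3 (-0.66), Gstm7 (-0.62), Stra6 (-0.62) and Tmem252 (-0.60), and Atp6v0c, of uncertain assignment. Osr2 had a difference of -0.73 (adjusted p = 0.0636), and passed under the 3 other scalings (adjusted p = 0.0142, 0.0317 and 0.0186, in a range of 0.0142 to 0.269 over alternatives with all libraries). In all 156 genes passed, 117 higher (75%) and 39 lower, and 95 of them also passed at E13.5, each in the same direction. The E13.5 libraries are part of this contrast, so the overlap is not independent.

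Among lists across both ages, osteogenesis had 5 of 17 members higher (Runx2, Alpl, Mef2c, Bmp3 and Dlx5), and 10 higher and 1 lower adjusted over the list alone. Its camera adjusted p was 2.6e-06, with adjusted p = 0.34 for an estimated correlation and adjusted p = 0.0321 for fry. Chondrogenesis had Sox6 and the cartilage collagen gene Col2a1 (1.62-fold) higher of 9 (7 adjusted over the list alone, camera adjusted p = 5.64e-05, and adjusted p = 0.772 with an estimated correlation). The BMP pathway (Bmp7, Bmp5 and Bmp3 higher of 24, 6 adjusted over the list alone), the Wnt pathway (Lgr5 and Tcf7 of 34, 9 adjusted over the list alone) and glycolysis and hypoxia (Eno1, of uncertain assignment, of 18, 1 adjusted over the list alone) were called up (adjusted p = 0.0302 each, and with an estimated correlation adjusted p = 0.772, 0.814 and 0.814). The retinoic acid pathway (Stra6 of 13, 2 lower adjusted over the list alone) and the erythroid list (no member of 9) were called down (adjusted p = 0.0059 and 0.0156, and with an estimated correlation adjusted p = 0.814 and 0.772). In the semaphorin list, which camera did not call (adjusted p = 0.833), Sema3a, Sema3d, Sema3e and Nrp2 rose and Nrp1 fell. As above, the osteogenesis, BMP and semaphorin lists are not independent evidence of direction. Erg, an endothelial marker, was 1.96-fold higher (adjusted p = 0.0235, and 0.0975 without the E12.5 mutant), and no other endothelial marker was at a level to be tested.

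The share of higher genes across both ages depended on the scaling. With libraries scaled to 1 FPKM sum there were 78 higher and 74 lower (51.3% higher), by median ratio 63 and 54 (53.8%), and by quantile 63 and 47 (57.3%), and 93 of the 156 genes (61 higher, 32 lower) passed under all 3. Most of the 156 genes lost their call in at least 1 leave-one-out fit. The count was 65 without E13.5 mutant replicate 1 and 79 without E13.5 control replicate 1. Col2a1 was called in 0 of 6 leave-one-out fits, with its highest adjusted p without E13.5 control replicate 2 (0.219). Tcf7, Tmem252, Stra6 and Darc, called in 1, 2, 3 and 3 of 6, had theirs without E13.5 control replicate 1 (0.186, 0.164, 0.121 and 0.0637), and Cadm3 and Sema3e, called in 2 and 3, without the E12.5 mutant (0.0725 and 0.071). Ebf3 and Gstm7, called in 2 and 3, had theirs without E13.5 mutant replicate 1 (0.0823 and 0.139). Atp6v0c, Mef2c, Nrp1, Osr1, Gria3 and Bmp5 lost their calls without E13.5 mutant replicate 1 (adjusted p = 0.0716, 0.0526, 0.0526, 0.117, 0.0568 and 0.0715), as did Bmp3 (0.168).

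The age contrast compares the 4 E13.5 libraries with the 2 E12.5 libraries, with genotype in the model. Without the E12.5 mutant, the age difference is that of the controls alone, so that fit leaves out more than a single library. Many extracellular matrix genes rose (34 of 51 tested) and G2 and M phase genes fell (18 of 29, but 1 of 29 without the E12.5 mutant), while neither list passed with an estimated correlation (camera adjusted p = 0.275 and 0.442). Igfbp5, an insulin-like growth factor binding protein gene, went from 4.71 ± 0.211 FPKM (SD, n = 2) at E12.5 to 38.5 ± 10.1 (SD, n = 4) at E13.5 (6.75-fold, adjusted p = 1.72e-05). Other large increases were in the annexin genes Anxa2 (6.09-fold) and Anxa1 (5.28-fold), Creb3l1 (5.36-fold), Col12a1 (4.94-fold), Shank1 (4.79-fold), Pcp4 (4.76-fold), the proteoglycan genes Dcn (4.74-fold) and Lum (4.48-fold), Igfbp3 (4.62-fold), Crabp1, a retinoic acid binding protein gene (4.53-fold), and Emp1 (4.48-fold). Smoc1, which encodes a secreted calcium-binding protein, fell from 14.3 ± 2.12 FPKM (SD, n = 2) to 2.68 ± 0.162 (SD, n = 4), a change of -2.05 (adjusted p = 1.72e-05). The other large decreases were in the embryonic globin gene Hbb-bh1 (-1.87), Kcnj2 (-1.86), Hbb-bt (-1.40), Cdr1 (-1.31), Asb4 (-1.29), the imprinted gene Peg10 (-1.19), Pcyt1a (-1.14), the histone genes Hist2h2ab and Hist1h2bg (-1.12 each) and Fli1 (-1.12), with Hba-a2 of uncertain assignment. Osr2 fell with age (-0.81, adjusted p = 0.0127) and Osr1 rose 3.79-fold (adjusted p = 0.000178). In all 1804 genes passed, 804 higher and 1000 lower, against 382 higher and 83 lower without the E12.5 mutant library.

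Of 51 tested extracellular matrix genes, 34 rose with age and none fell, among them Eln (3.58-fold), Cd44 (3.41-fold), Lox (3.01-fold), Postn (2.50-fold) and Col1a1 (2.07-fold), and 37 rose and 1 fell when adjusted over the list alone (camera adjusted p = 6.76e-20, and with an estimated correlation adjusted p = 0.275). Of 29 G2 and M phase genes, 18 fell and none rose (26 adjusted over the list alone), with Ccnb2 at -0.80 (camera adjusted p = 7.99e-09, and with an estimated correlation adjusted p = 0.442). Of 29 S phase genes, 10 fell, with Fen1 at -0.73, and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.00226, and with an estimated correlation adjusted p = 0.56). The erythroid list had 6 of 9 lower, among them Hbb-b1 (-1.20) and Slc4a1 (-1.01), with 7 adjusted over the list alone (camera adjusted p = 0.00011, and with an estimated correlation adjusted p = 0.363).

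Osteogenesis had 8 of 17 members higher with age and 2 lower (11 and 3 adjusted over the list alone), including Bmp3 (2.98-fold), Alpl (2.68-fold) and Sparc (2.11-fold), with a camera adjusted p of 0.00014 and, with an estimated correlation, an adjusted p of 0.293. TGF-beta pathway genes rose in 7 of 18 (7 adjusted over the list alone), with Tgfb2 2.11-fold higher (camera adjusted p = 0.000269, and with an estimated correlation adjusted p = 0.293). Dissociation and stress response genes rose in 6 of 20 (6 higher and 1 lower adjusted over the list alone), among them Klf4 (2.88-fold), Fos (2.80-fold), Myc (2.28-fold) and Jun (1.75-fold), with a camera adjusted p of 0.000245 and, with an estimated correlation, an adjusted p of 0.42. Camera also called up the BMP pathway (8 higher and 1 lower of 24, 10 and 2 adjusted over the list alone, adjusted p = 0.00226), the retinoic acid pathway (5 and 2 of 13, the same counts adjusted over the list alone, adjusted p = 0.00606), pericyte and smooth muscle markers (2 of 5, 2 adjusted over the list alone, adjusted p = 0.00645), glycolysis and hypoxia (4 of 18, 5 adjusted over the list alone, adjusted p = 0.0231) and the semaphorin list (8 and 2 of 25, 9 and 4 adjusted over the list alone, adjusted p = 0.0383). With an estimated correlation these 5 had adjusted p of 0.372, 0.56, 0.319, 0.56 and 0.56. Among them, Crabp2 (1.95-fold), the ligand gene Bmp2 (log2 0.48) and Ldha, of lactate production (2.20-fold), rose.

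Camera did not call the remaining lists for age. Higher and lower members were 10 and 6 of 34 in the Wnt pathway, with Wif1 (2.09-fold) and Dkk1 (-1.13), 3 and 4 of 18 in the Hedgehog pathway, 5 and 4 of 16 in the FGF pathway and 5 and 2 of 9 in the Notch pathway. They were 3 and 2 of 9 in chondrogenesis, with Col9a2 (2.38-fold) and Col2a1 (-0.70), 8 and 7 of 35 among palate and facial transcription factors, with Tfap2b (2.20-fold) and Tbx2 (-0.94), and 3 and 4 of 18 in tooth mesenchyme. They were 3 and 1 of 14 among CDK inhibitors, with Cdkn1c (1.55-fold), 0 and 1 of 16 among ephrins and Eph receptors, with Epha7 (-0.57), and 0 of 19 in cholesterol synthesis (limma). In the sex-linked list the Y-linked genes Ddx3y, Eif2s3y and Kdm5d were higher and Xist lower (camera adjusted p = 0.157), and these calls follow which libraries have Xist.

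**Figure D3:**
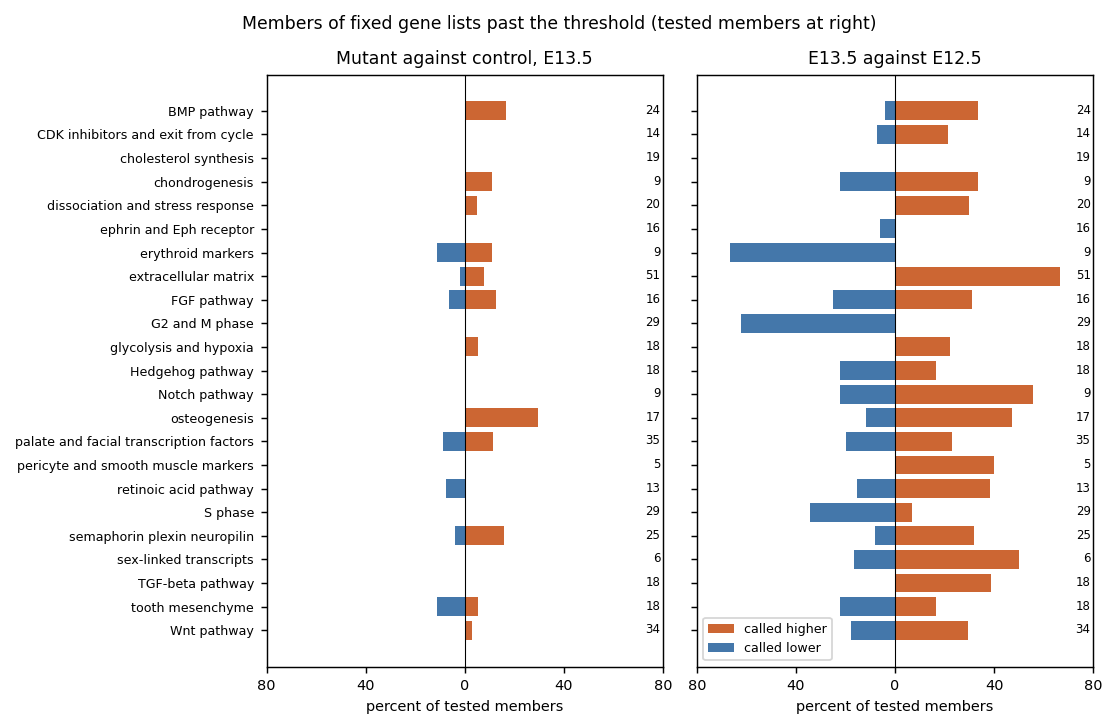
Bars give the percent of tested members of each list past the threshold, higher to the right and lower to the left of 0, for mutant against control at E13.5 (left) and E13.5 against E12.5 (right), with the number of tested members at the right edge. The 23 lists with at least 5 tested members are shown, and 34 of 51 extracellular matrix genes are higher with age.

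The 2 ages differ in title number, so age cannot be told apart from whatever that number marks. Without the E12.5 mutant the age difference is that of the controls alone, and without the E12.5 control that of the mutants alone. Fewer calls in those fits therefore need not mean that the library left out carries the result. The age count was 465 without the E12.5 mutant (82.2% higher), 718 without the E12.5 control (46.1% higher) and 1201 without E13.5 control replicate 1, and 248 of the 1804 genes passed in all 6 leave-one-out fits. Without the E12.5 mutant and without the E12.5 control, 26 and 21 of 51 extracellular matrix genes were still called higher (medians 0.71 and 0.59), and 1 and 3 of 29 G2 and M phase genes (medians -0.40 and -0.53) and 0 and 2 of 29 S phase genes lower. Without the E12.5 mutant the calls of Hbb-bt, Asb4, Peg10, Hist2h2ab, Hist1h2bg and Fen1 were lost (adjusted p = 0.0687, 0.0529, 0.116, 0.0548, 0.121 and 0.0704), as were those of Osr2, Cdkn1c, Epha7, Col2a1 and Bmp2 (0.162, 0.0914, 0.312, 0.1005 and 0.107), and Hba-a2 lost its call without the E12.5 control (0.0759). The share of higher genes was 44.6% as deposited, and 59.1%, 61.6% and 52.5% with libraries scaled to 1 FPKM sum, by median ratio and by quantile.

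The interaction asks whether the genotype difference changed between the ages. It was past the threshold for 4 genes (3 higher, 1 lower, with 627 at an unadjusted p under 0.05), all of uncertain assignment: Hba-a2, Hba-a1 and the short transcripts Mir1931 and Snora28, the last 2 named here because the count is small. With the robust prior 25 genes passed (11 higher, 14 lower), and 7 (3 higher, 4 lower) in the fit without genes of uncertain assignment, added after the data were seen. In simulated data of this design no interaction of up to 4-fold was recovered.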

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

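The tests of summed gene copies below were chosen after the result was seen. The difference in genotype effect between the ages (E13.5 minus E12.5, log2) was past the threshold of the limma interaction for 4 genes: -10.34 for Hba-a1, 4.49 for Hba-a2, 2.82 for Mir1931 and 6.55 for Snora28.

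Hba-a1 and Hba-a2, near-identical alpha globin genes, took opposite values in the same libraries. Hba-a1 had 42.8 FPKM in the E12.5 mutant, 47.6 and 30.5 in the E13.5 controls and at most 0.279 in the other 3 libraries, while Hba-a2 had 0.551 and 1.71 FPKM in the E13.5 controls and 23.8 or more elsewhere. A candidate explanation is that reads were split between the copies differently in each library: with both symbols summed, the interaction was -0.5 (adjusted p = 0.887), with sums of 110.3 and 99.99 FPKM at E12.5, 38.8 and 23.9 in E13.5 mutants and 48.1 and 32.2 in E13.5 controls. Atp6v0c, called lower in mutants, gave the same picture with Atp6v0c-ps2, with a genotype difference across both ages of 0.06 for the sum (adjusted p = 0.802) against -3.74 for Atp6v0c alone. A difference in globin RNA between the genotypes is not excluded by these sums, and a biological explanation was not tested.

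Mir1931, a transcript of 119 bases, was listed at 7.24 and 5.02 FPKM in the E13.5 mutants and at 0 in the other 4 libraries. Snora28, of 121 bases, was listed at 21.3 and 14.9 FPKM in the E13.5 mutants, 3.95 in the E12.5 control and 0 in the other 3 libraries.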

How the results depend on the processing

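The fits without genes of uncertain assignment and without genes on X and Y were chosen after the data were seen. At E13.5 the fits without an E12.5 library and with the E13.5 libraries alone leave the differences unchanged, and they are among the values counted here. For the genes named at E13.5, 1172 of 1424 values kept their direction and side of the threshold, 247 were no longer past it, 5 newly passed and 0 reversed. Across both ages these were 1184, 190, 21 and 1 of 1396, and for age 1882, 195, 5 and 0 of 2082. For the interaction 25 of 32 kept theirs and 7 were no longer past it. The 1 reversed value was that of Ephb1 across both ages, 0.34 with transcripts summed and -0.474 (adjusted p = 0.595) with the transcript of highest mean alone, and the cause was not tested. With no filter on low values, 0 genes passed at E13.5 and 0 across both ages (1519 and 1953 at an unadjusted p under 0.05, limma), 681 for age and 13 for the interaction, and limma's prior degrees of freedom at E13.5 went from 7.04 to 1.47. With a mean of at least 1 FPKM there were 81 at E13.5 and 11 for the interaction, and with a mean of at least 5 FPKM, where fewer genes were tested, 54 at E13.5, 93 across both ages and 993 for age. With the robust prior these were 261, 263 and, for the interaction, 25, and without genes of uncertain assignment 249, 258 and 7 (the 4 interaction genes being left out), with prior degrees of freedom of 12.14 at E13.5. With the transcript of highest mean alone there were 37 at E13.5, 69 across both ages and 1032 for age, where 21 of the 1791 age calls it tested changed sign. Limma treat at 0.5, a stricter hypothesis, left 24 at E13.5. Median ratio scaling gave 77 and quantile normalization 87 at E13.5, and 2 each for the interaction. At E12.5 the genes higher by at least 1 numbered 21 with a pseudocount of 5, 25 with 1 FPKM sum, 27 after quantile normalization and 64 with the transcript of highest mean, and those lower 25 with 1 FPKM sum and 27 with the transcript of highest mean. No list passed with an estimated correlation (0 at E13.5, 0 across both ages, 0 for age), and with fry 0, 1 and 7 passed. With 2 residual degrees of freedom at E13.5 and 3 in the additive fit, even a strongly changed list could hardly pass with an estimated correlation. Leaving out each library in turn gave 75 to 192 genes at E13.5 (75 without control replicate 2, and 192 without mutant replicate 1, which leaves title number 3048 alone), 65 to 159 across both ages, 465 to 1713 for age (465, with 382 higher and 83 lower, without the E12.5 mutant) and 13 to 37 for the interaction, which cannot be fitted without an E12.5 library. The lone library of a group is assumed to vary like the others. Without an E12.5 library, the age difference comes from the genotype still present at E12.5, and the genotype difference across both ages is that of E13.5. Except where fewer genes or libraries or the prior are named, the cause was not tested. Of the 139 genes at E13.5, 75 passed under all 3 scalings and 27 under all 10 changes of pseudocount, mean filter, scaling, prior and transcript that tested them, and of 156 across both ages 93 and 58. The files give no counts, so what depth limits at low FPKM is unknown.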

Other observations

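The scaling tests below and the tests of markers for the lower genes were chosen after the result was seen. Penk, which encodes proenkephalin, was among the most abundant genes that rose in mutants: it had 364 against 122 FPKM at E12.5 and was 2.26-fold higher at E13.5 (SE 0.153 on the log2 scale, adjusted p = 0.00787, n = 2 each in the limma fit). Ddx26b and Mtus1, singled out at E12.5, were also higher at E13.5 (adjusted p = 0.00157 and 0.0288). Mecom, a transcription factor gene with separate loci under its symbol, fell with age (-1.32, adjusted p = 0.00134) and was 2.78-fold higher in mutants across both ages. Erg, which encodes an ETS factor, had 8.39 FPKM in the E12.5 mutant against 2.54 in the control, and at E13.5 3.79 and 5.81 in mutants against 2.63 and 2.17 in controls, with Pecam1 at most 0.133 FPKM in any library. The genes of this paragraph, apart from those that the rule names, were chosen after their values were seen.

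The matched random lists of this paragraph are drawn within the single E12.5 pair, so they do not measure spread between libraries. Genes called at E13.5 tended to differ in the same direction in the E12.5 pair (76 of 92 higher and 43 of 47 lower, relative to the median gene). Sex of the embryos alone does not account for this: without E13.5 mutant replicate 2, the one E13.5 library with Xist, 59 of 83 genes called higher and 39 of 42 called lower still had the same direction at E12.5, above the highest of 10000 matched random lists (54 and 30). That refit rests on a single E13.5 mutant library, whose title number (3047) differs from that of the E13.5 controls (3048). Scaling is argued against for the higher genes, with at least 84.4% in the same direction under each of 3 scalings (40 of 47, 65 of 77 and 47 of 54, random highest 36, 44 and 40). For the lower genes, of which fewer were called, at least 81.8% had the same direction (25 of 30, 33 of 37 and 27 of 33). These counts were above the random medians (16, 24 and 16), but above the random highest (27, 34 and 26) only after quantile normalization. For the lower genes scaling and genotype therefore cannot be told apart by this test, and the higher and lower genes are not shown to differ in this. For other cell types passing the sort, the epithelium, endothelium, leukocyte, glia, neuron and muscle marker sums were compared with the called genes. At E13.5 the list that rose most (neuron) rose by 32.6 FPKM against 760 FPKM summed over the higher genes. For the lower genes (-322 FPKM) the largest decrease among these lists at E13.5 was a change of -2.1 FPKM. In the E12.5 pair the neuron sum changed by 10.2 FPKM and the leukocyte sum by -3.21 FPKM. Most of these sums were too low in every library to approach those of the called genes, so the comparison cannot decide. Erythroid cells also stay open for the lower genes, since their markers changed by -179 FPKM at E13.5 but had 744 FPKM in the E12.5 mutant and 699 in the control (39 of 44 genes were lower relative to these markers in the E12.5 mutant, and 44 and 5 in E13.5 mutant replicates 1 and 2), and the mix of mesenchymal cells among RFP+ cells, which may differ by genotype, and the parents or litters of the embryos were not tested.

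Genes that differed by genotype across both ages in part changed with age too: 51 of the 117 higher genes rose with age and 12 fell, and of the 39 lower genes 15 rose and 7 fell. These contrasts come from 1 fit, and a gene higher only in E13.5 mutants can enter both, so the overlap was not tested. One hypothesis is that mutant cells were further along the whole change from E12.5 to E13.5. Over 1699 genes called by age and not by genotype, the slope of the genotype difference on the age difference was -0.055 for the E13.5 libraries and -0.069 for the E12.5 pair (-0.021 and -0.045 over all genes called by age), which argues against it, since an advance of the whole change needs a positive slope. That part of the change with age, such as osteogenesis genes, is advanced in mutants stays open, and the 15 lower genes that rise with age, Igf1 and Osr1 among them, go the other way.

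Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as 156 genes across both ages, and the highest other split gave 8. That other split put both E12.5 libraries on the same side. With age in the model it compared E13.5 mutant replicate 2 with the remaining E13.5 libraries, unlike the real split. Among splits with an E12.5 library on each side, the highest other gave 2. With 10 splits, or the fewer that are like the real one, a share under 0.05 cannot be reached.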
